A study of Arabidopsis thaliana with 13 samples.

How the data were processed

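RNA from Arabidopsis plants harvested at different hours was compared on 13 spotted cDNA arrays with 2 colours, each of which set RNA from 1 time against RNA from another. Per the labels, 5 arrays compared 12 h with 0 h, 2 compared 6 h with 0 h, 2 compared 18 h with 0 h, and 1 each compared 24 h with 0 h, 36 h with 24 h, 36 h with 24 h in the dark, and 60 h with 48 h. The plants of the last array had grown in cycles of 12 h light and 12 h dark and were moved to continuous light 24 and 36 h before the harvests. The labels give no light condition for the other array that compared 36 h with 24 h. Hours of light and dark are stated only for the 60 h array. They are not given for the arrays of 6, 12, 18 and 24 h either. Groups were taken from the labels of both channels. The title of 1 of the arrays that compared 6 h with 0 h lists the times in the other order than its channels, and the channels were followed.

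The deposited values are 1 log2 ratio per feature and array. Per the labels, the authors read the arrays with ScanAlyze 2.33, 2.42 or 2.44; how they corrected background and normalised the ratios is not given in the sources used here. The log base was settled from the values, since ratios of small whole numbers pile up at their log2: the value for a ratio of 1/2 occurs 159 times, against a mean of 20.6 times at the neighbouring steps, and there is no such excess at the natural logs. The median log2 ratio per array runs from -0.147 to 0.06. Whether each ratio is channel 2 over channel 1 is not given in the sources used here. It was read that way, and this direction is called likely: the other reading turns every higher and lower in the text. The basis is the usual form of such ratios and the array labelled dark, on which the 3 measured genes of a list of dark- and starvation-induced genes were higher at the later time and the Calvin cycle genes lower. The planned check of direction with dawn and evening clock genes could not be run, because 0 of the 4 dawn and 0 of the 8 evening genes had a named feature.

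Of the 12800 features, 5197 were assigned to a single gene by the platform annotation, 214 to several genes and 7389 were not listed, so these last are unnamed here. Symbols were updated through the TAIR10.1 gene table, which matched 5190 of the 5197 features. Features of 1 gene were averaged per array, which gave 3689 named genes, and each feature without a single gene was kept as a target of its own. No positions are given, since the genome build behind the array is not given in the sources used here. Targets with a value on at least 10 of the 13 arrays were tested, which kept 11290 of 11292.

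Log2 ratios were centred on each array's median and turned to the later over the earlier time. A linear model with 1 coefficient per pair of times and 1 dye term, coded by which channel held the later time, was fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3. All arrays share 1 estimate of the spread per target, so a comparison with a single array is tested on the assumption that the lone array varies like the others. Only 6 h and 12 h had arrays of both channel orders, so the dye correction of every other comparison came from those. Their arrays with the later time in channel 1 were all read with ScanAlyze 2.33, while the arrays of 36 h and 60 h were read with 2.44. Targets with a Benjamini-Hochberg adjusted p under 0.05 are called. A moderated F-test covered 6, 12 and 18 h together, and contrasts tested whether the changes from 24 to 36 h and from 48 to 60 h differ from the change from 0 to 12 h. Errors after ± are standard errors of the coefficient unless SD is named. Nothing in the labels says that arrays of 1 comparison came from separately grown plants, apart from the word biological on 3 of them, so the p-values measure the spread between arrays, which may be partly technical. The number of arrays limits the precision.

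A total of 18 gene lists with 219 members were fixed before the data were examined, of which 23 members were measured. Lists with at least 3 measured members, 6 in all, were tested with camera at a preset inter-gene correlation of 0.01, with the estimated correlation and fry beside it. Camera tests a list against the other genes, while fry tests it against no change. The lists of starch metabolism, of phenylpropanoid and flavonoid synthesis, and of root markers had 1 measured member each. The other 9 lists had 0: dawn, evening and other clock genes, cell wall expansion, nitrogen and sulphur assimilation, handling response, seed storage, flower organ and cytosolic ribosomal protein genes. The ribosomal list came from a search of gene synonyms and held only 7 members, so its 0 does not cover ribosomal protein genes in general. The genes named in the text follow a rule also fixed before the data were examined. For 12 h against 0 h these are the 10 largest changes each way among called genes with a symbol that moved the same way on every array. The rule takes the 8 largest each way for 6 h and for 18 h, the 5 largest each way for a comparison with 1 array besides the values of the genes named at 12 h, and up to 4 members of each list with the smallest p. Where fewer passed, all that passed were named.

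The model was tested on simulated data with known changes in the real layout of arrays, with 100 targets changed by log2 1 and 100 by log2 2 in each comparison. For 12 h against 0 h it recovered 76% of the smaller and 98% of the larger changes. For 6 h the shares were 12% and 90%, and for 18 h 4% and 77%. With a single array, no comparison recovered a change of log2 1, and changes of log2 2 were recovered for 33% at 36 h in the dark, 29% at 36 h, 29% at 24 h and 1% at 60 h. Of the simulated calls, 5.43% were false at 12 h, 5.56% at 6 h, 3.57% at 18 h, 6.45% at 24 h, 9.38% at 36 h, 10.8% at 36 h in the dark and 0% at 60 h, where there was 1 call. The simulated noise was normal, independent between arrays and of the same spread on every array, with 1 dye term. The SD of the real arrays ran from 0.382 to 0.858. The recovered and false shares therefore need not hold for the real calls, least of all for single arrays.

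Alternatives were run without the dye term, with a separate dye term for ScanAlyze 2.33, without centring, with arrays scaled to 1 spread, with other minimums of arrays, without averaging features, with the 3 oldest-version arrays for 12 h averaged, with the doubtful 6 h array turned, with stricter thresholds, within software versions, and without each array of the replicated comparisons. Figures were drawn with Python 3.11.15.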

Results

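The series addresses which Arabidopsis genes change in transcript level over the day and which go on changing when the light-dark cycle is removed. Each of the 13 arrays compared RNA of 2 times in 2 colours, with 5 arrays for 12 h against 0 h, 2 each for 6 h and 18 h against 0 h, and 1 for each other pair of times. Arrays gave a ratio for 12446 to 12795 of the 12800 features. The SD of the log2 ratios was 0.382 on array 1 of 12 h against 0 h and lay between 0.626 and 0.858 on the other 12 arrays. On that array 2.07% of features were more than 2-fold from the array's median, against 12.5% to 18.4% on the other 4 arrays of the comparison. Between pairs of features of 1 gene, the correlation across genes was 0.131 on that array and 0.259 to 0.652 on the others. Comparisons with 1 array have no replicates.

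The change from 0 to 12 h was the main comparison, and signs are those of the later over the earlier time with ratios read as channel 2 over channel 1, which is likely but not stated. CHL (AT3G47860), which encodes a lipocalin of the chloroplast, rose by log2 1.81 ± 0.28 (SE, n = 5 arrays, adjusted p = 0.0259), which is 3.52-fold. AT3G24450 rose by 2.31 ± 0.40 (adjusted p = 0.0269) and AT4G09500 by 1.96 ± 0.29 (adjusted p = 0.0259). AKINBETA1 (AT5G21170), a regulatory subunit of the energy-sensing kinase SnRK1, fell 2.63-fold (SE 0.23 on the log2 scale, adjusted p = 0.0259). TZP (AT5G43630), which acts in light-dependent growth, fell by 1.53 ± 0.29 (adjusted p = 0.0298). RCA (AT2G39730), the activase of Rubisco, fell by 1.11 ± 0.23 (adjusted p = 0.0362, 9 features). AT2G18970 fell by 1.64 ± 0.27 and AT4G27450 fell by 1.61 ± 0.26, both at adjusted p = 0.0259. The other genes with the largest rises were AT1G78110, AT3G27700, AT1G12760, AT2G41090, AT4G30660, AT1G33970 and AT2G44500, between 1.31 and 1.68. The other genes with the largest falls were AT5G28740, AT4G32480, AT4G37560, AT5G28750 and AT3G51010, between -1.36 and -1.10.

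In all, 464 of 11290 targets passed at 12 h, 208 higher and 256 lower, of which 50 and 64 are named genes. Of these, 305 moved the same way on all 5 arrays and 306 changed at least 2-fold. The calls rest on few arrays: without array 1 there were 1063, which hold all of the 464 with the same sign, and without array 2, 3, 4 or 5 there were 0. There was 1 call without the dye term, 202 with arrays scaled to 1 spread, 109 with a separate dye term for the oldest scanning software, and 0 with the 3 arrays of that software averaged or with array 2 of 6 h turned. Within software versions, the arrays of ScanAlyze 2.33 gave 1229 calls and those of 2.44, without a dye term, gave 0. Either fit leaves only 1 residual degree of freedom per target. The 2.44 arrays of 12 h are array 1 and array 2 alone, with an r of 0.0004 between them. The 2 counts therefore do not show an effect of the software.

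**Figure D1:**
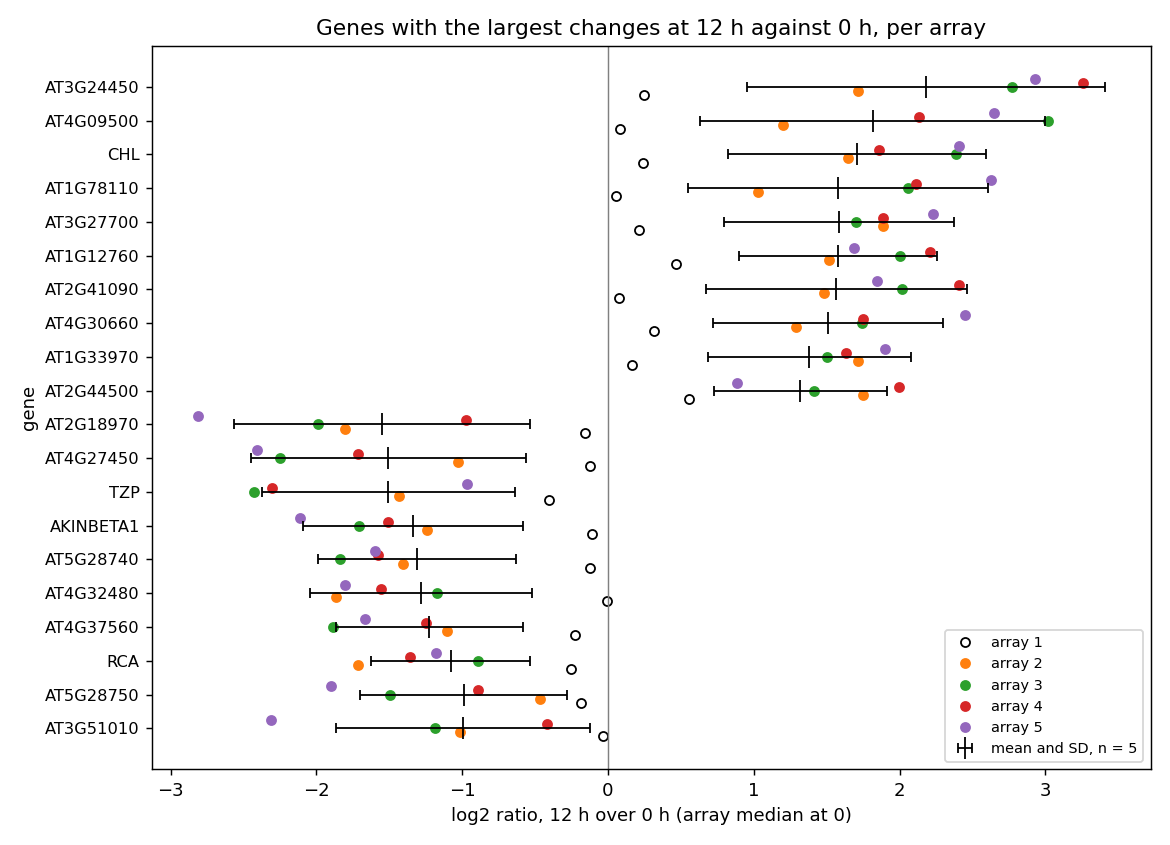
Log2 ratio of 12 h over 0 h for the 20 genes named for that comparison, with 1 point per array and the mean and SD of the 5 arrays. Array 1 (open points) lies near 0 for most genes, such as 0.21 for AT3G27700, where the other 4 arrays lie between 1.70 and 2.23.

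Among the gene lists at 12 h, genes of the cold and dehydration response were higher than other genes, with a median log2 change of 1.08 over 3 members (camera adjusted p = 0.00577). None of the list calls of any comparison held with an estimated correlation: at 12 h the adjusted p = 0.147 with an estimated correlation for cold, Calvin cycle, dark-induced and photorespiration genes, 0.249 for the antenna and 0.233 for photosystem subunits. The dehydrin gene COR47 rose by 1.08 ± 0.23 (adjusted p = 0.0355), while KIN2 at 1.74 ± 0.47 did not pass over all genes (adjusted p = 0.0722). The Calvin cycle genes had a median of -0.57 (adjusted p = 0.00922), with RCA called. Photorespiration genes had a median of -0.37 (adjusted p = 0.0442), with HPR, a hydroxypyruvate reductase, down at -0.76 ± 0.16 (adjusted p = 0.0355). Medians were -0.52 for the light-harvesting antenna (adjusted p = 0.0219), -0.51 for photosystem core subunits (adjusted p = 0.0130) and -0.56 for dark- and starvation-induced genes (adjusted p = 0.0132). Over all genes 1 cold, 1 Calvin cycle and 1 photorespiration member passed and 0 of the other 3 lists, and adjusted over the list alone 3 cold, 3 Calvin cycle, 1 photorespiration, 2 antenna, 2 photosystem and 2 dark-induced members passed. PWD, a starch-degradation enzyme and the only measured member of its list, rose by 1.52 ± 0.33 (adjusted p = 0.0385). HCT, of phenylpropanoid synthesis, at -0.30 and the root marker PYK10 at -0.06 were not called. By fry, the antenna (adjusted p = 0.0837) and photosystem lists (adjusted p = 0.0647) did not pass. Photorespiration no longer passed camera without array 1 (adjusted p = 0.108), array 3 (0.0720) or array 4 (0.0636) of 12 h, without array 1 (0.0523) or array 2 (0.0524) of 6 h, or with a separate dye term for the oldest software (adjusted p = 0.116). The antenna no longer passed without array 3 (adjusted p = 0.0825) or array 4 (0.07845) of 12 h.

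At 6 h against 0 h, AT3G62550 rose by 3.15 ± 0.34 (n = 2 arrays, adjusted p = 0.0457), which is 8.86-fold. It also rose at 12 h, by 1.11 (adjusted p = 0.0303). COR47 stood at 1.98 ± 0.35 and did not pass (adjusted p = 0.0586), nor did SBPASE, a Calvin cycle phosphatase, at -1.14 ± 0.25 (adjusted p = 0.0735). AT3G62550 was the 1 call among 11290 targets, with 1688 at an unadjusted p under 0.05. The cold genes had a median of 1.68 and the Calvin cycle genes of -0.75 (both camera adjusted p = 0.0184), and photorespiration genes of -0.70 (adjusted p = 0.0129). With an estimated correlation the adjusted p = 0.164 with an estimated correlation for cold, 0.221 for the Calvin cycle and 0.161 for photorespiration. Adjusted over the list alone, 1 cold, 2 Calvin cycle and 3 photorespiration members passed, and over all genes 0. Of the 464 targets called at 12 h, 454 had the same sign at 6 h, 381 at 18 h and 382 at 24 h, and the r across genes with the 12 h change was 0.645, 0.311 and 0.2645. All of these comparisons share 0 h as the reference, so they can agree through 0 h alone, and genes are not independent replicates. The likeness also went with the channel order on 2 of the 3 arrays of 18 and 24 h and on array 2 of 6 h. Those arrays were all read with ScanAlyze 2.33, as were arrays 3, 4 and 5 of 12 h. Array 1 of 6 h was read with 2.44 and array 1 of 18 h with 2.42. The pattern therefore also went with the software version. Before dye correction, the 24 h array had an r of 0.594 and 0.283 with arrays 4 and 2 of 12 h, of its own order, and of -0.192 and -0.245 with arrays 3 and 5, of the other order. For array 2 of 18 h these were 0.603 and 0.5205 with arrays 3 and 5, of its own order, and -0.0349 and 0.122 with arrays 4 and 2, of the other. For array 1 of 18 h they were 0.135 and 0.164 with arrays 3 and 5, of its own order, and 0.214 and 0.243 with arrays 4 and 2. Array 2 of 6 h had an r of 0.696 and 0.5585 with arrays 3 and 5, of its own order. With arrays 4 and 2 it had 0.0379 and 0.216. Array 1 of 6 h had 0.447 and 0.416 with arrays 4 and 2, of its own order. With arrays 3 and 5 it had 0.421 and 0.256. With no effect simulated the r of 6 h with 12 h was 0.0038, but this simulation had no shared 0 h RNA. The count of calls at 6 h was 98 with values on all 13 arrays, 58 with features not averaged, 8 with arrays scaled to 1 spread, 4 without the dye term, and 0 without centring, with a separate dye term, with the 3 oldest-software arrays averaged or with array 2 of 6 h turned. It was 272 without array 1 of 12 h, 7 without array 2, 8 without array 4, 9 without either array of 18 h, and 0 without array 3 or 5 of 12 h or either array of 6 h. Turned by their channel labels, the 2 arrays of 6 h, of opposite channel order, had an r of 0.405 across targets. Turning array 2 would reverse the sign of this r, so it goes with the channel labels rather than the title.

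At 18 h against 0 h, light-harvesting antenna genes were lower than other genes, with a median of -1.01 over 4 members (n = 2 arrays, camera adjusted p = 4.43e-05). Photosystem core subunits had a median of -0.89 (adjusted p = 0.00056). Neither list held by camera with an estimated correlation (adjusted p = 0.284 for both). Neither passed fry, which tests against no change rather than other genes (adjusted p = 0.241 for the antenna and 0.290 for photosystem subunits). Across targets, the r between the 2 arrays of 18 h was only 0.126, although they share the channel order. Both had the later time in channel 1, so their dye correction came wholly from other comparisons, as for every comparison with a single array. LHB1B2, an antenna protein gene with 13 features and near-identical paralogs, stood at -1.31 ± 0.38 (adjusted p = 0.602) and LHCB4.2 at -1.18 ± 0.37 (adjusted p = 0.680). Adjusted over the list alone 3 antenna and 0 photosystem members passed, and over all genes 0 of either. limma called 0 of 11290 targets, with 676 at an unadjusted p under 0.05. There were 12 calls without array 1 of 12 h and 156 without array 2 of 18 h.

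Over 6, 12 and 18 h together, the F-test called 394 of 11290 targets. It called 908 without array 1 of 12 h, 93 without array 4, and 0 without array 2, 3 or 5 of 12 h or without either array of 6 h. It called 193 without the dye term, 250 with arrays scaled to 1 spread, 1 with a separate dye term, and 0 with the 3 oldest-software arrays averaged or with array 2 of 6 h turned. At 24 h against 0 h, 1 day apart, the antenna genes had a median of -1.24 (1 array, camera adjusted p = 0.000107; adjusted p = 0.383 with an estimated correlation and 0.591 by fry), with 0 members called over all genes and 0 adjusted over the list alone. Of single targets, 2 unnamed features passed, chosen here after their values were seen, at -3.99 and -4.92, of 11273 tested, with 363 at an unadjusted p under 0.05. The count was 1 without array 4 of 12 h and 0 without array 3 or 5 of 12 h or either array of 6 h. It was 21 with arrays scaled to 1 spread, 1 with a separate dye term, and 0 without the dye term, without centring, with values on all 13 arrays, with the 3 oldest-software arrays averaged or with array 2 of 6 h turned.

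At 36 h against 24 h in the dark, the 3 measured genes of the dark- and starvation-induced list, which encode enzymes of leucine breakdown, were called. MCCA (AT1G03090) rose by 3.50 ± 0.49 (1 array, adjusted p = 0.0157), IVD (AT3G45300) by 3.24 ± 0.59 (adjusted p = 0.0313) and MCCB (AT4G34030) by 2.45 ± 0.37 (adjusted p = 0.0167). CaS (AT5G23060), a thylakoid calcium-sensing protein, fell by 3.76 ± 0.40 (adjusted p = 0.0128), which is 13.5-fold. SBPASE fell by 2.92 ± 0.38 (adjusted p = 0.0139) and AT1G11860, of the photorespiration list, by 2.48 ± 0.36 (adjusted p = 0.0157). SIS rose by 3.22 ± 0.43 (adjusted p = 0.0139), AT1G21400 by 3.07 and AT1G19530 by 2.91, while AT4G16980 fell by 3.67, AT1G70280 fell by 3.20, AT5G33370 fell by 3.18 and AT2G10940 fell by 3.16. The dark- and starvation-induced list had a median of 3.24 (camera adjusted p = 8.46e-06, 3 of 3 members higher over all genes and 3 adjusted over the list alone; adjusted p = 0.0779 with an estimated correlation). The direction of these 3 genes and of the Calvin cycle genes on this array was part of the basis for reading the ratios as channel 2 over channel 1, so it is no independent result, while the size of their change is not set by that choice. The Calvin cycle list had a median of -1.68 (adjusted p = 0.000592, 1 lower over all genes and 3 adjusted over the list alone) and the cold list of 2.12 (adjusted p = 0.0145, 0 and 1). The adjusted p = 0.0997 with an estimated correlation for these 2 lists. In all 243 of 11248 targets passed, 104 higher and 139 lower, with 24 and 31 named genes. The count was 77 without array 3 of 12 h, 81 without array 5, 94 without either array of 6 h, 68 with a separate dye term, 10 with array 2 of 6 h turned, 0 with arrays scaled to 1 spread, and 0 with the 3 oldest-software arrays averaged.

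At 36 h against 24 h without a stated light condition, MCCA rose by 3.19 ± 0.49 (1 array, adjusted p = 0.0230) and MCCB by 3.01 ± 0.37 (adjusted p = 0.0179), while IVD at 2.85 ± 0.59 did not pass (adjusted p = 0.0503). AT5G56220 rose by 5.29 ± 0.47 (adjusted p = 0.00903), which is 39.2-fold, and stood at -0.08 on the dark array. AT1G69890 rose by 3.81, SIS by 3.22 and AT3G10300 by 3.06. CaS fell by 2.96 ± 0.40 (adjusted p = 0.0179), AT2G17660 fell by 3.17, AT3G19330 fell by 2.91, EXO fell by 2.90 and AT4G16980 fell by 2.78. SBPASE fell by 2.57 (adjusted p = 0.0211), PRK fell by 2.05 (adjusted p = 0.0461) and AT1G11860 fell 4.59-fold (adjusted p = 0.0285). The dark-induced list had a median of 3.01 (camera adjusted p = 1.84e-05, 2 higher over all genes and 3 adjusted over the list alone), the Calvin cycle list of -2.05 (adjusted p = 0.00061, 2 and 3) and the cold list of 1.41 (adjusted p = 0.0374, 0 and 1). The adjusted p = 0.0885 with an estimated correlation for the dark-induced list, 0.137 for the Calvin cycle and 0.148 for cold. The cold list did not pass by fry (adjusted p = 0.0695) or with a separate dye term for the oldest software (adjusted p = 0.139). In all 174 of 11285 targets passed, 93 higher and 81 lower. The count was 35 without array 3 of 12 h, 101 without array 4, 26 without array 5, 15 without either array of 6 h, 21 with a separate dye term, 13 with array 2 of 6 h turned, 0 with arrays scaled to 1 spread, and 0 with the 3 oldest-software arrays averaged. Of the calls of both comparisons from 24 to 36 h, 43 higher and 58 lower were shared, where independent lists would share 0.86 and 1. The lists are not independent even without a common effect. All comparisons share 1 estimate of the spread per target, so the excess may be overstated. They also share the dye term, which works the other way for these 2 arrays of opposite channel order. With no effect simulated, the r between these 2 comparisons was -0.129.

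**Figure D2:**
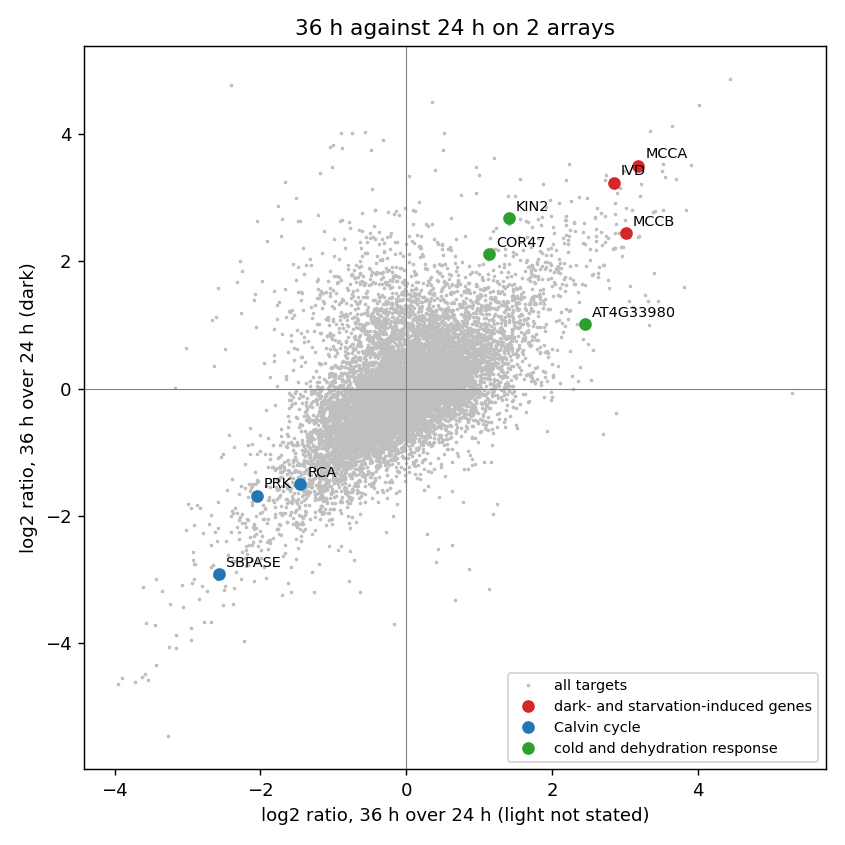
Fitted log2 ratio of 36 h over 24 h for every target, without a stated light condition (horizontal axis) and in the dark (vertical axis), with 1 small point per target and members of 3 gene lists in colour. MCCA lies at 3.19 and 3.50 and SBPASE at -2.57 and -2.92, while AT5G56220 lies at 5.29 and -0.08.

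At 60 h against 48 h in continuous light, AT5G63000 rose by 3.30 ± 0.41 (1 array, adjusted p = 0.0106), which is 9.88-fold. AT1G14710 rose 8.02-fold (adjusted p = 0.0366), AT1G53430 by log2 2.40 (adjusted p = 0.0448), AT3G49960 by 2.31 (adjusted p = 0.0493) and AT2G40920 by 2.16 (adjusted p = 0.0465). The value of AT2G40920 averages 2 features that disagree, since only 1 had the sign of the average at 60 h. At 12 h these features stood at -0.56 and 0.92. AT5G42825 fell by 3.23 ± 0.53 (adjusted p = 0.0334). RCA stood at 0.72 ± 0.55 and was not called. The Calvin cycle list had a median of 0.72 and the photosystem list of 0.76 (both camera adjusted p = 0.0267), with 0 members passing over all genes and 0 adjusted over the list alone. The adjusted p = 0.390 with an estimated correlation for the Calvin cycle and 0.412 for the photosystem list. Neither list passed by fry (adjusted p = 0.314 and 0.511) or, by camera, with a separate dye term for the oldest software (both adjusted p = 0.0653) or with the 3 oldest-software arrays averaged (both adjusted p = 0.124, with a Calvin cycle median of 0.46). With arrays scaled to 1 spread the medians were 1.21 and 1.16, and both passed. The dark-induced list had a median of 0.04, a mean of -0.19 and a test direction of lower, and was not called. In all 65 of 11104 targets passed, 56 higher and 9 lower, of which 5 and 1 are named genes. The called log2 changes reached 8.38 and -8.41. On this array the r between pairs of features of 1 gene was only 0.259, and 202 features had no value. Whether the channels of this array are in the order labelled is left open, and with the array turned every rise and fall at 60 h is reversed, with 9 higher and 56 lower. The count was 25 without array 3 of 12 h, 27 without array 5 and 29 without either array of 6 h. It was 188 with arrays scaled to 1 spread, 23 without the dye term, 31 with a separate dye term, 33 with array 2 of 6 h turned and 18 with the 3 oldest-software arrays averaged.

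**Figure D3:**
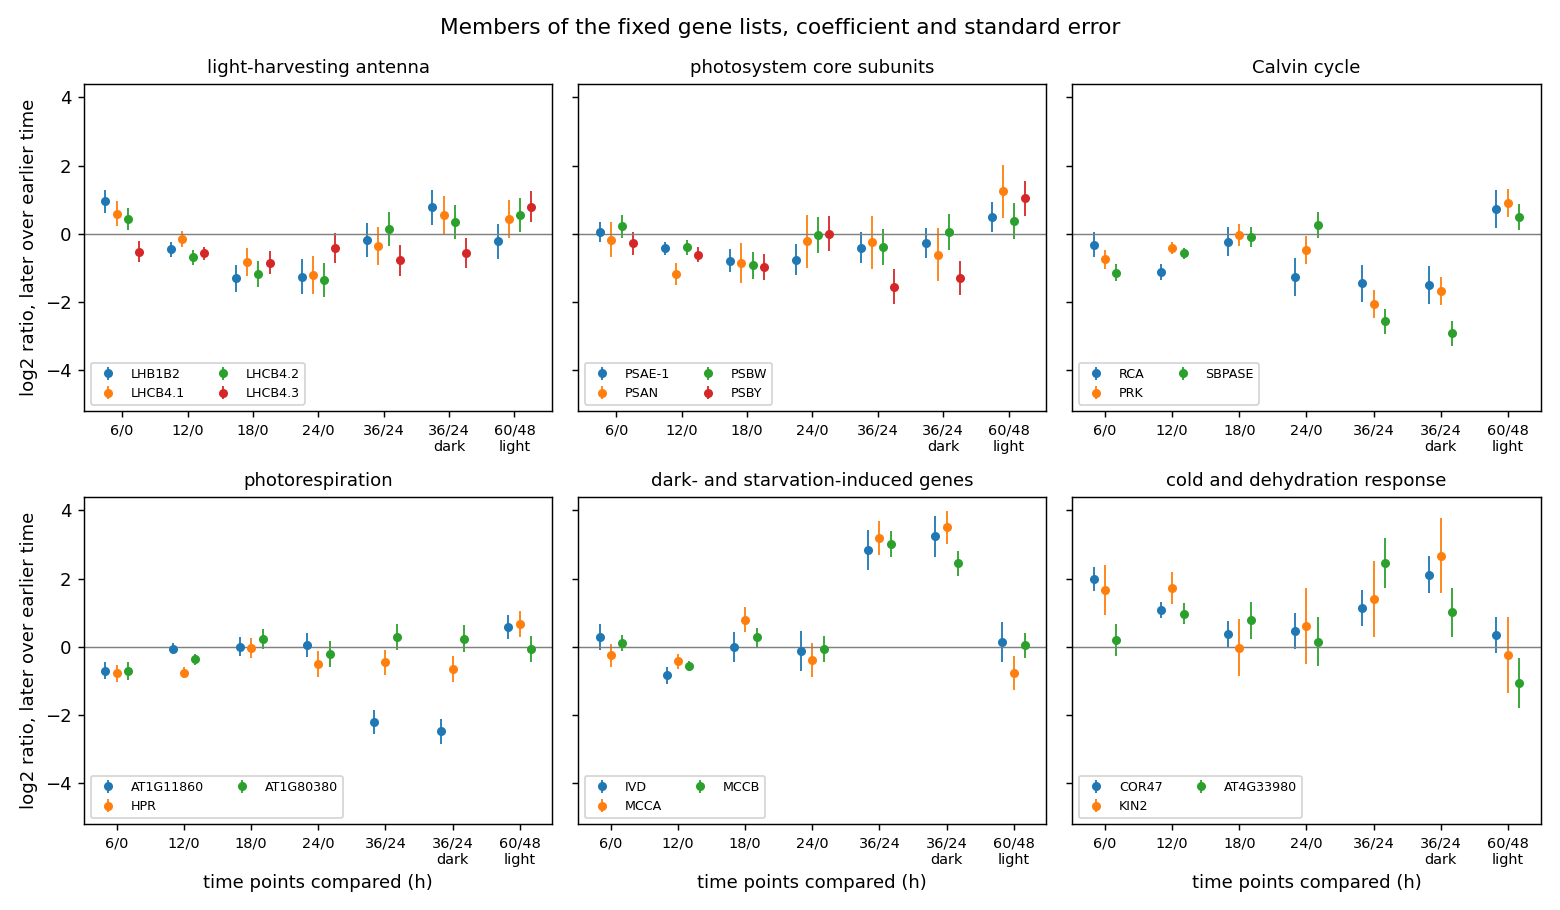
Fitted log2 ratio of the later over the earlier time (vertical axis) for the members of 6 gene lists in 7 comparisons (horizontal axis), with 1 point per gene and bars for the standard error. The dark- and starvation-induced genes stand between 2.45 and 3.50 in both comparisons of 36 h with 24 h.

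Tests of the differences asked whether the 12-h change was altered. Between 24 to 36 h in the dark and 0 to 12 h, the changes of AKINBETA1 and AT4G27450 differed by 3.01 and 3.23, since both fell from 0 to 12 h and stood at 1.61 and 1.62 in the dark. The change of IVD differed by 4.07 and that of CaS by -2.87. In all 172 of 11248 targets differed in the dark, 145 of 11285 at 36 h without a stated light and 48 of 11104 in continuous light. Without array 1 of 12 h these counts were 365, 248 and 161. In the dark the count was 31 without array 2 of 12 h, 18 without array 3, 28 without array 4, 18 without array 5 and 19 without either array of 6 h. At 36 h without a stated light it was 0 without array 3 or 5 of 12 h, 64 without array 4 and 35 without either array of 6 h. In continuous light it was 25 without array 3 of 12 h, 29 without array 5 and 21 without either array of 6 h. With arrays scaled to 1 spread the counts were 0 in the dark, 0 at 36 h and 165 in continuous light, with the 3 oldest-software arrays averaged 0, 0 and 16, and with array 2 of 6 h turned 21, 1 and 25. Without the dye term they were 61 at 36 h and 15 in continuous light, and with a separate dye term 0 at 36 h. The count in continuous light also depends on the channel order of the 60 h array, which is left open, and with that array turned it was 29, with 4 higher and 25 lower.

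Of the 464 targets called at 12 h, 319 moved the same way from 24 to 36 h in the dark, or 68.8% (95% exact binomial interval 64.3% to 72.9%, counting error only). In continuous light 211 did, or 45.5% (40.9% to 50.1%), and at 36 h without a stated light 246 did, or 53.0% (48.4% to 57.6%). With the 12 h values taken only from arrays of the opposite channel order and no dye correction on either side, the counts were 271 in the dark, 116 in continuous light and 300 at 36 h. Across genes, the r with the 12 h change was 0.159 in the dark, 0.0268 in continuous light and 0.0732 at 36 h; with no effect simulated it was 0.0458, 0.0452 and -0.0675. Before dye correction, the r with the mean of the 12 h arrays of the other and of the same channel order was 0.106 and -0.00653 in the dark, -0.106 and -0.0491 in continuous light, and -0.00319 and 0.235 at 36 h. Without array 1 of 12 h the share in the dark was 49.3% and that in continuous light 40.8%, and without either array of 6 h the latter was 54.8%. With arrays scaled to 1 spread it was 28.7% (58 of 202) and with a 2-fold minimum 37.6%. With a separate dye term for the oldest software the shares were 80.6% in the dark, 66.7% in continuous light and 36.7% at 36 h. In the dark, 10 higher and 21 lower calls were shared with 12 h, where independent lists would share 1.92 and 3.16. At 36 h without a stated light 5 and 11 were, where 1.71 and 1.84 would be, and in continuous light 0 and 0 were, where 1.05 and 0.207 would be. These lists also share 1 estimate of the spread per target and the dye term, so they are not independent even without a common effect.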

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

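The tests of the explanations weighed here were chosen after the results were seen, apart from the turning of the 12 h arrays, which was set out before.

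Array 1 of 12 h against 0 h lay far from the other 4 arrays of the comparison. Its SD of log2 ratios was 0.382, against 0.694 to 0.799, and its values were 0.21 for AT3G27700 (others 1.70 to 2.23), 0.17 for AT1G33970 (others 1.5 to 1.9), -0.13 for AT5G28740 (-1.84 to -1.41) and 0.33 for PSAE-1 (-0.70 to -0.42). These were 5 of 41 sets of values tested, and all 5 name this array. The genes had been chosen for large 12 h changes or, from the lists, for a small p, and all sets share the same 5 arrays. An array with little change tends to stand apart on such genes. The test's chance rate of about 1 in 20 therefore does not apply, and the 5 are not separate evidence.

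Over the 1063 targets called without that array, its ratios had an r of -0.0397 (95% interval -0.0996 to 0.0205) with the mean of the other 4. Over all targets, its r with each of the other 4 lay between -0.0506 and 0.0689, where those among the other 4 lay between 0.114 and 0.571. The r of -0.0397 argues against the same RNAs with compressed ratios, and the SD of 0.382 argues against values placed at the wrong features, which would leave the spread as it was. RNA of like expression in both channels remains a candidate explanation, since the r of -0.0397 is what it needs. Its title differs from the others in the word single, whose meaning is not given in the sources used here. No biological explanation was tested.

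The array of 36 h against 24 h without a stated light condition resembled the dark array of the same times. Their turned ratios had an r of 0.71 (0.700 to 0.719, 11244 targets), which a dye bias per feature would have made negative, since the channel orders are opposite. An ordinary change of the light-dark day is argued against by the median of the dark-induced list, which lay 3.57 above that at 12 h. Plants kept in the dark on both arrays may explain the likeness, since the lowest of the 3 members on either array was 2.68, with the ratios read as channel 2 over channel 1. The light of the first array is not given in the sources used here.

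Targets called at 12 h tended to run the other way at 60 h against 48 h when the ratios of the 60 h array were not corrected for dye, with 116 of 464 in the same direction. Among 72 of them with a dye coefficient under 0.1, the share was 25% (15.5% to 36.6%), which a dye bias alone would have brought near 50%. Corrected for dye, the share over the 464 was 45.5% (40.9% to 50.1%) with 1 dye term and 47.6% (43.0% to 52.3%) with separate dye terms, which goes with a dye bias. Among the targets called with separate dye terms it was 66.7%, and without either array of 6 h 54.8%. These intervals treat targets on 1 array as independent, which they are not. A dye bias and channels in the other order than labelled therefore cannot be told apart by the 25% and these shares, and both stay open. A shifted phase in continuous light was not tested and stays open too.

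Of the 16 ways to turn the 5 arrays of 12 h, only the labelled way gave 464 calls. The highest other gave 463, which turned arrays 2 to 5 together against array 1, and every remaining way gave 0. So few ways cannot give a share under 0.05.

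Tested differences between changes were found for 172 targets between the dark and 12 h, 145 between 36 h and 12 h and 48 between 60 h and 12 h. In the dark these were 3.23 for AT4G27450, 3.01 for AKINBETA1, 3.90 for SIS, 3.93 for MCCA, 4.07 for IVD, 3.01 for MCCB, 3.28 for AT1G21400 and 2.96 for AT1G19530. They were -2.87 for CaS, -3.11 for AT3G19330, -3.13 for AT4G16980, -3.43 for AT1G70280, -3.55 for AT5G33370, -2.75 for AT2G10940, -2.22 for AT2G40920, -2.35 for SBPASE and -2.43 for AT1G11860. At 36 h without a stated light they were 4.05 for AT4G27450, 3.40 for AKINBETA1, 3.49 for AT3G51010, 4.84 for AT5G56220, 4.03 for AT1G69890, 3.90 for SIS, 3.61 for MCCA, 3.68 for IVD, 3.11 for AT1G21400 and 3.57 for MCCB. They were -3.34 for AT2G17660, -3.02 for AT3G19330 and -2.15 for AT1G11860. In continuous light they were 3.08 for AT5G63000 and 2.58 for AT1G53430. With the 60 h array turned they were -3.53 (adjusted p = 0.0163) and -2.22, which did not pass (adjusted p = 0.129), and 29 targets differed.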

How the results depend on the processing

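Chosen after seeing the data were the settings without array 1 of 12 h and with a separate dye term, without the dark array or the array of unstated light, with the 60 h array turned, and the estimated correlation for the dark comparison. Each named gene was followed only in the comparison that named it, or for list members in the comparison with the smallest p. There, in the planned settings that cover all comparisons, no value called in the main fit or in the setting changed direction. Changes of direction of values called in neither were not counted, so no kept direction is shown for those. The 60 h genes reversed with the 60 h array turned. Named genes were not followed within software versions or in the other settings chosen after seeing the data. In planned settings other than leaving out an array, 490 values kept their side of the threshold, 245 lost it and 2 gained it, and without single arrays 430, 167 and 6 did. Where results moved, the cause was not tested unless given. The planned direction test on clock genes was not run, since 0 were measured. No paired analysis was possible because the labels share no replicate numbers between arrays. Signal over background was not analysed here.

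Without the dye term, calls were 1 at 12 h, 4 at 6 h, 0 at 24 h, 23 at 60 h and 193 over 6, 12 and 18 h. Differences from 12 h were 15 at 60 h and 61 at 36 h, and the share of 12 h calls with the same direction, then over 1 target, was 100% in the dark, 100% at 36 h and 0% at 60 h. Without centring, calls were 0 at 6 h and 0 at 24 h; the median of all targets in the dark moved from -0.02 to 0.11.

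With arrays scaled to 1 spread, calls were 202 at 12 h, 8 at 6 h, 21 at 24 h, 0 at 36 h, 0 in the dark, 188 at 60 h and 250 over 6, 12 and 18 h. Differences from 12 h were 0 in the dark, 165 at 60 h and 0 at 36 h, and the shares were 28.7% at 60 h and 61.4% at 36 h. With targets measured on all 13 arrays, calls were 98 at 6 h and 0 at 24 h. With features not averaged, there were 58 at 6 h.

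With the 3 oldest-software arrays of 12 h averaged, which leaves fewer arrays, calls were 0 at 12 h, 0 at 6 h, 0 at 24 h, 0 at 36 h, 0 in the dark, 18 at 60 h and 0 over 6, 12 and 18 h. Differences were 0 in the dark, 16 at 60 h and 0 at 36 h. No share could be given with 0 calls.

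With array 2 of 6 h turned, calls were 0 at 12 h, 0 at 6 h, 0 at 24 h, 13 at 36 h, 10 in the dark, 33 at 60 h and 0 over 6, 12 and 18 h. Differences were 21 in the dark, 25 at 60 h and 1 at 36 h.

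With a separate dye term for the oldest software, calls were 109 at 12 h, 0 at 6 h, 1 at 24 h, 21 at 36 h, 68 in the dark, 31 at 60 h and 1 over 6, 12 and 18 h. Differences were 0 at 36 h, and shares 80.6% in the dark, 66.7% at 60 h and 36.7% at 36 h.

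At an adjusted p under 0.01, a stricter threshold by construction, calls were 0 at 12 h, 0 at 6 h, 0 at 24 h, 1 at 36 h, 0 in the dark, 16 at 60 h and 0 over 6, 12 and 18 h. Differences were 0 in the dark, 15 at 60 h and 0 at 36 h. With a 2-fold minimum, calls were 306 at 12 h and the shares 37.6% at 60 h and 58.8% at 36 h.

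Within the oldest software, calls at 12 h were 1229, and within the newest, without dye term, 0, both with only 1 residual degree of freedom per target. Without array 1 and with a separate dye term they were 887. With the 60 h array turned, calls at 60 h were 9 higher and 56 lower, differences from 12 h were 29, and the share was 54.5%, the mirror image of 45.5% by construction, since turning a lone array flips every sign. With the estimated correlation, list calls were 0 at 12 h and 0 in the dark.

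Leaving out each array gave 0 to 1063 calls at 12 h, 0 to 272 at 6 h, 0 to 156 at 18 h, 0 to 2 at 24 h, 15 to 215 at 36 h, 77 to 361 in the dark, 25 to 80 at 60 h and 0 to 908 over 6, 12 and 18 h. Differences ranged from 18 to 365 in the dark, 21 to 161 at 60 h and 0 to 248 at 36 h. List calls at 12 h ranged from 4 to 6. The shares ranged from 49.3% to 74.5% in the dark, where the lowest crossed to the other direction, from 40.8% to 54.8% at 60 h and from 49.5% to 56.4% at 36 h.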

Other observations

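The families of genes with related symbols were chosen after the data were seen, as 49 tests of 7 families in 7 comparisons.

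The alpha-tubulin genes TUA1, TUA2, TUA3, TUA5 and TUA6, which encode subunits of microtubules, had a median of 0.73 at 12 h against 0 h (0.34 to 1.03). All 5 were above 0, and TUA5 at 1.03 (adjusted p = 0.0374) and TUA6 at 1.03 (adjusted p = 0.0288) were called. The camera test gave adjusted p = 0.00154, and adjusted p = 0.398 with an estimated correlation. The median was 0.68 with arrays scaled to 1 spread, 0.76 without centring and 0.92 without array 1. At 36 h against 24 h without a stated light the median was -1.03, with 0 of 5 above 0 and 0 called, and the family did not pass (adjusted p = 0.0814, and 0.644 with an estimated correlation). Without the dye term the median there was -0.61, with 1 of 5 above 0, and the difference from 12 h was not tested. In the dark the median was -0.37, with 1 of 5 above 0 (adjusted p = 0.801). Near-identical members share sequence, so their features are not independent.

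Autophagy genes (ATG3, ATG8F, ATG8C, ATG8E, ATG8D, APG8A and APG8H) had a median of 1.13 at 36 h against 24 h in the dark (0.28 to 1.55), with 7 of 7 above 0 and 0 called. The camera test gave adjusted p = 0.00181, and adjusted p = 0.488 with an estimated correlation. The median was 0.94 with arrays scaled to 1 spread and 1.26 without centring. At 36 h without a stated light it was 0.98, with 6 of 7 above 0 (adjusted p = 0.148). At 18 h against 0 h it was 0.38, again with 7 of 7 above 0 (camera adjusted p = 0.0813, and 0.693 with an estimated correlation). All members but ATG3 carry ATG8 or APG8 symbols, so their features may not be independent.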
